A study of Drosophila melanogaster with 14 samples.

How the data were processed

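Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts and tags open DNA, in wing imaginal discs of Drosophila melanogaster, the larval tissue that forms the adult wing. Per the labels' protocols, 10 discs were used for each genotype and condition, nuclei were incubated with transposase for 30 min, and libraries were amplified for 13 PCR cycles. Groups were read from the labels: discs in which cell death had been induced ("regenerating") and discs without it ("control") at 0, 15 and 25 h, and undamaged larval discs outside the time course (L3). Each of the 7 groups had 2 libraries. The labels name the replicates only by number and do not say whether they came from separate animals or cultures. Permutation p-values over libraries therefore measure the spread between these libraries, which may be technical. P-values from counts of regions or genes measure no spread between libraries.

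The deposited files were peak lists, 1 for nucleosome-free fragments and 1 for mononucleosome fragments of each of the 14 libraries. The peaks used here were thus called per library, and whether pooled samples were also called is not given. STAR 2.4.0j, MACS2 and the dm6 build are named in the submitters' processing notes. The fragment length limits, the peak threshold, the treatment of transposase offset and the use of a control track are not given in the sources used here. Each deposited peak carried a fold enrichment over the caller's background, a −log10 p-value, a −log10 q-value and a score, all the authors' own values. The deposited score equalled 10 times the −log10 q-value, rounded down to a whole number, in 99.997% of peaks, and the lowest −log10 q in any list lay between 2.00 and 2.22. Fold and score were used to rank or filter peaks within their own list and were not compared between libraries, except that fold entered the estimate of depth described next. The peaks lay on 6 chromosome arms.

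Read depth is not recorded in peak lists. Fold and p of each deposited peak were solved for the whole-number pile-up at the summit and for the local background that give both values under the Poisson model of the caller, with a tolerance of 0.001 on the log10 p scale. The lowest solved background of each list, taken as the genome background, gave a relative depth per library, 1.62 to 3.67 fragments for nucleosome-free fragments. These counts carry counting error only.

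Peaks of the 14 libraries were merged where they overlapped by at least 1 bp or touched, separately for each fragment class, in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9), and a library had a region if it had a peak in it. A region was gained with damage at a time if both regenerating and neither control library of that time had it, and lost if the reverse held. The same rule gave opened and closed regions between control times and between L3 and control discs. Counts were set beside those of the other 2 ways to split the same 4 libraries into pairs. With 3 splits at 1 time no share can fall below 0.333, so the test was made on the 3 times together, over all 27 combinations of within-time splits (exact permutation, smallest share 0.037). Regions gained at 2 or more times were compared with all 216 within-time label orders, one-sided (smallest p 0.00463). Peak numbers and other properties of the lists were tested over the same orders, two-sided (smallest p 0.00926), with Benjamini-Hochberg adjustment over 7 properties per fragment class.

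Coordinates are 1-based on Release 6 of the genome (dm6). Annotation was BDGP 6.54 of Ensembl release 115, with 17206 genes and 5809 transposable elements. A region belonged to the gene with the nearest transcription start, and to a promoter if it lay within 200 bp of a start. Promoter shares were tested by Fisher's exact test per time and pooled by Mantel-Haenszel, against all other regions present in at least 2 of the 4 libraries of that time. For 20 motifs, matches within 200 bp around the strongest summit were compared by Fisher's exact test with Benjamini-Hochberg adjustment over the motifs. For 19 gene lists (248 symbols, of which 2 were matched through older names and 2 not at all), the number of genes with a gained or lost region was compared with 10000 random lists matched on regions per gene, one-sided, with adjustment over the lists. Regions are not independent replicates in these tests.

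Groups, tests, lists, motifs and most alternatives were set before the data were examined, as was the rule for named regions: per time the 10 gained and 5 lost regions of highest rank, the 10 highest-ranking regions gained at all 3 times, up to 4 examples per gene list, and all regions of rpr, hid, wg, Wnt6, puc, Mmp1, Ilp8, upd3, Ets21C and nub. Rank was the lower of the 2 replicates' percentiles of the authors' fold within its list. The 13 regions lost at all 3 times were added after the values were seen.

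Alternatives chosen in advance were peaks with −log10 q of at least 5, equal list lengths, peaks covering at least 50% of a region, regions built from summits within 100 bp, an asymmetric threshold, each library left out, a replicate block, promoters within 1000 bp, a 400 bp motif window, 5 GC strata, and genes extended by 5000 bp. Alternatives chosen after seeing the data were the removal of regions in transposable elements, a comparison with regions found in 1 library of each group, and a depth filter in 2 forms. The filter kept a gained or lost region only if its pile-up, scaled to each library of the other group and lowered by 2 counting errors, would have reached that library's lowest listed p. The first form used the genome background. It let weak regions of high local background pass, so a form with the local background was added, and both are given because they differ.

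The calculations were tested on simulated data. Merging gave the same 33226 regions as bedtools 2.31.1, and the pile-up was solved for all 4974 simulated peaks. When 200 regions present in every library were set to the background in simulated controls, 200, 198 and 200 were called gained at 0, 15 and 25 h. When they were only 4-fold lower in controls, 42, 43 and 36 were called, so the presence rule misses most partial changes at strong regions. With no difference but depth between the simulated libraries, 552 regions were called gained and 57 lost at 0 h, 190 and 281 at 15 h, and 196 and 275 at 25 h, and 23 of the 27 combined splits parted as many regions as the real one. The simulated counts carried Poisson error only, with no other spread between replicates. A planted gene list and a planted motif were each the only one called among 20. In that simulation fewer genes had a called region by chance than in the data, where 7.30 of 16 Wnt genes were expected to have a gained one. The planted motif was also more frequent than most motifs in the data. The power of the list and motif tests in the data was therefore not measured.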

Results

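Wing discs were profiled at 0, 15 and 25 h after cell death was induced, with undamaged controls at each time and a further group of undamaged larval discs (L3). The series asks how accessible chromatin changes from the earliest response to damage until the disc is patterned anew. The 14 libraries fell into 7 groups of 2. They listed 19174 to 24139 nucleosome-free peaks, which mark short fragments from open DNA, and 11145 to 13387 mononucleosome peaks, which mark fragments that span a nucleosome.

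Many open regions of the wing disc were shared between all libraries. The promoter regions of rpr and hid, inducers of cell death, of the Wnt ligands wg and Wnt6, of puc, a phosphatase that limits JNK signalling, of Mmp1, a secreted matrix protease, of Ilp8, a relaxin-like hormone released by damaged discs, and of nub, a POU factor of the wing, each had a peak in every library, damaged or not. The nucleosome-free peaks merged into 33226 regions with a median width of 188 bp, of which 13545 (40.8%) were in all 14 libraries and 4984 (15.0%) in 1. Promoters made up 42.1% of the regions in all libraries and 11.9% of those in 1. Replicates shared a median of 77.9% of their combined regions (Jaccard index, 7 pairs, 72.4 to 78.7%), and libraries of the same time but other treatment 74.0% (12 pairs, 71.4 to 77.0%). The other 72 pairs had a median of 74.3% (68.8 to 80.1%), so replicates were not always the closest libraries. The 0 h control replicates shared 72.4%, while control replicate 2 shared 76.0 and 75.0% with the regenerating libraries of that time.

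Regenerating discs listed more nucleosome-free peaks than controls, 23071 ± 973 against 21383 ± 1469 (SD, n = 6 each), with exact permutation p = 0.0463 before and 0.130 after adjustment over 7 properties. The number of peaks followed the depth of the library: across the 14 libraries it rose with the background pile-up (Pearson r = 0.873, permutation p = 6e-05, adjusted p = 0.00036; Spearman rho = 0.807, permutation p = 0.00082; 6 relations computed). Without the pair of libraries farthest from the median background r was 0.819. Within the 6 controls r was 0.916 (exact permutation p = 0.0264) and within the 6 regenerating libraries 0.633 (exact permutation p = 0.179). The background was 3.13 ± 0.367 fragments in regenerating and 2.61 ± 0.637 in control libraries (SD, n = 6 each; exact permutation p = 0.120). Mononucleosome peak numbers were 12583 ± 821 and 12450 ± 801 (SD, n = 6 each; exact permutation p = 0.806).

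**Figure D1:**
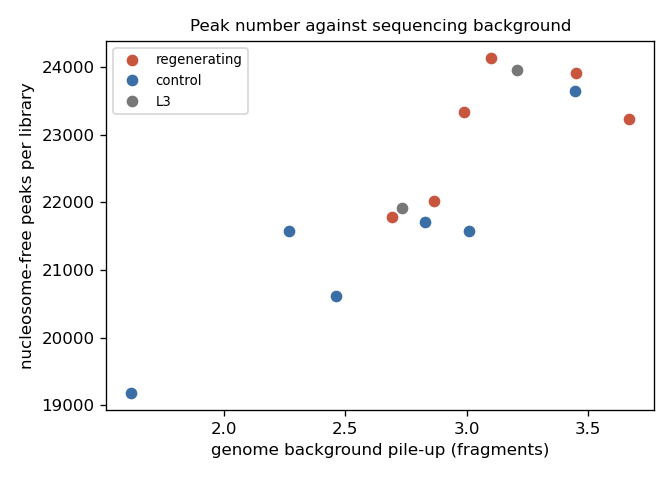
Number of nucleosome-free peaks in each of the 14 libraries (vertical axis) against the background pile-up in fragments (horizontal axis), coloured by regenerating, control and L3. Peak number rose with the background (r = 0.873), and the library with the lowest background, 1.62, had the shortest list, 19174 peaks.

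At 0 h, directly after the induction of cell death, the strongest gained regions included several in repeats and near centromeres or telomeres. A telomeric TART-C element on chromosome 4 (1288515 to 1289093, intergenic, 56632 bp from Cadps) ranked at or above the 99.3rd percentile of the fold in both regenerating lists, and was absent from both 0 h controls but present in all later controls. Others were a blood element in an intron of CG43163 (3L, 8505446 to 8505579), an intron of l(3)80Fg in pericentromeric 3L (25971148 to 25971370) and a springer element in an intron of CG15465 on X (5100503 to 5100638). A coding exon at the start of CG16888 (2L, 13813128 to 13813306) was in all 6 regenerating and no control library. The strongest lost region, 3L 15297326 to 15297537, lay in a gypsy5 element 1421 bp from Best4, with the authors' fold at 46.8 and 55.9 in the 0 h controls.

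In all, 1200 nucleosome-free regions were gained and 185 lost at 0 h, together 6.24% of the 22190 regions present in at least 2 of the 4 libraries. The other splits of these 4 libraries parted 937 and 859 regions, the former 837 in one direction and 100 in the other. With equal list lengths 572 were gained and 430 lost. With the depth filter, added after the data were seen, 190 and 81 remained against the genome background and 33 and 46 against the local background. Under the genome form these 271 compare with 239 in the higher other split, and under the local form another split parted more, 92 against 79. Leaving out 1 library, which relaxes the criterion, gave 3158 gained and 341 lost regions without regenerating replicate 1, and 2160 and 671 without regenerating replicate 2. It gave 1983 and 1356 without control replicate 1, and 3203 and 684 without control replicate 2.

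At 15 h the strongest gained regions again included a telomeric TART-A element on chromosome 4 (1343408 to 1343956, 92.4th percentile), absent only from the 15 h controls. An intron of speck at its transcription start (2R, 24146793 to 24147107), an intron of the receptor phosphatase gene Ptp99A (3R, 29441222 to 29441468) and an intron of l(3)80Fj (3L, 27994356 to 27994498) were in all 6 regenerating and none of the 8 undamaged libraries. A region in the 3′ UTR of Mer, a Hippo pathway gene (X, 19690086 to 19690433), was gained at 15 and 25 h and present in both 0 h controls. Among lost regions, the gypsy5 region near Best4 led again, followed by an intron of Dbp80 (3L, 27356290 to 27356409) and an invader4 element 5053 bp from Map205 (3R, 32073494 to 32073630).

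At this time 732 regions were gained and 582 lost, and the other splits parted 1155 and 763. The depth filters turned the balance, with 131 gained and 230 lost against the genome background (in all 361, higher other split 263), and 42 and 141 against the local background (183, other 73). Without regenerating replicate 1 or 2 the numbers were 2446 and 968 or 1773 and 1790, and without control replicate 1 or 2 they were 1218 and 2254 or 2007 and 1540.

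At 25 h, when re-patterning is complete per the series description, an intron of l(3)80Fg (88.0th percentile), a TART-A element (chromosome 4, 1330494 to 1331483), a blood element in the piRNA locus flam (X, 21730560 to 21730720) and the 5′ UTR of indra (3L, 1342138 to 1342232) were among the strongest gained regions. Of the 8 undamaged libraries, 2, 4, 5 and 2 had these regions, none of them a 25 h control. The 10 gained regions of highest rank at each time were all in all 6 regenerating libraries. Their presence in regenerating discs was thus not particular to a time. An intergenic region 1184 bp from the homeobox gene HGTX (3L, 14600724 to 14600879) was in all 6 regenerating and none of the undamaged libraries. The lost regions included the 5′ UTR of Mad, the transcription factor of the Dpp pathway (2L, 3159595 to 3159689, 78.4th percentile), which had a peak in all 8 undamaged and 3 of the 6 regenerating libraries. A region in an intron of smash, 60 bp from a start (3R, 4705914 to 4706086), was in all 8 undamaged libraries and no regenerating one.

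At 25 h 1172 regions were gained and 295 lost, and the other splits parted 703 and 713. Gained regions outnumbered lost ones under each setting tried, by 414 to 124 and 248 to 52 under the genome and local forms of the depth filter (538 and 300 in all, higher other splits 274 and 93), and by 647 to 517 with equal list lengths. Without regenerating replicate 1 or 2 the numbers were 2573 and 569 or 3021 and 907, and without control replicate 1 or 2 they were 1925 and 1290 or 2292 and 864.

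**Figure D2:**
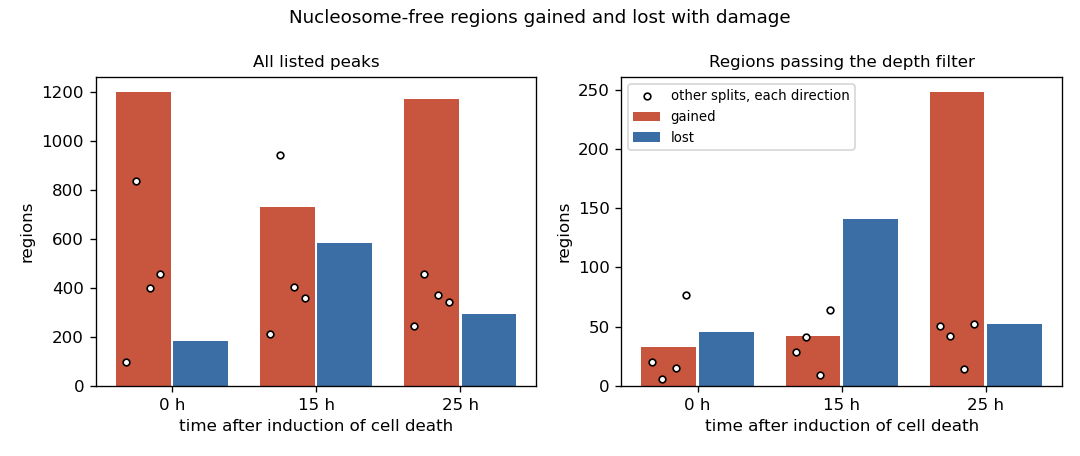
Nucleosome-free regions gained and lost with damage (bars) at 0, 15 and 25 h, for all listed peaks and for regions passing the local form of the depth filter. Open circles give both directions of the other splits of the same 4 libraries. At 0 h gains exceed losses 1200 to 185 before the filter and not after it, 33 to 46, while at 25 h they exceed them in both panels, 1172 to 295 and 248 to 52.

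Summed over the times, damage parted 4166 nucleosome-free regions, more than any of the other 26 combinations of splits, of which the highest parted 4007 (exact permutation share 0.037, the smallest possible). With the local form of the depth filter 562 were parted and the highest other combination parted 575 (exact permutation share 0.0741). Of mononucleosome regions 2093 were parted, and the highest other combination parted 2321 (exact permutation share 0.185). At single times 233 mononucleosome regions were gained and 284 lost at 0 h, 482 and 198 at 15 h, and 445 and 451 at 25 h. Another split of the same libraries parted more at 0 h (717 against 517) and 15 h (708 against 680), while at 25 h the higher other split parted 441 against 896, where 1 time allows no share below 0.333. Under the genome and local forms of the depth filter the numbers were 81 and 113 or 46 and 58 at 0 h, 114 and 106 or 58 and 89 at 15 h, and 317 and 144 or 279 and 36 at 25 h (461 and 315 in all, higher other splits 123 and 33).

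Where nucleosome-free regions were gained, mononucleosome peaks were more often found in regenerating libraries only, and where they were lost, in control libraries only. Of the regions gained at 0, 15 and 25 h, 48, 46 and 43 had a mononucleosome peak in both regenerating and neither control library, and 10, 2 and 17 the reverse (exact binomial tests, adjusted p = 8.13e-07, 2.51e-11 and 0.00137). Of the lost regions 1, 6 and 1 had it in the regenerating and 16, 18 and 34 in the control libraries (exact binomial tests, adjusted p = 0.000412, 0.0255 and 4.71e-09). Regions with a nucleosome-free peak in all 4 libraries had 111 against 140, 283 against 86 and 171 against 354 at the 3 times (exact binomial tests, adjusted p = 0.0770, 1.08e-24 and 4.57e-15). The tests took an even split as the null, from which these regions departed at 15 and 25 h. Gained and lost regions were not tested against them, and both fragment classes came from the same libraries.

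The same regions were gained repeatedly. An intergenic stretch near the tip of X (39297 to 40320), the speck intron, the HGTX region, an intergenic region in pericentromeric 3L (26161192 to 26161370) and a non-coding exon of lncRNA:CR40469 (X, 122560 to 122709) led the 56 regions gained at all 3 times. Regions gained at 2 or more times numbered 369, against a median of 51.5 over label orders and 338 in the highest other order (exact permutation p = 0.00463, one-sided, the smallest possible). Between 0 and 25 h 211 regions were shared where independent lists would share 28.3, and each time had its own controls. The independent lists include regions with a peak in all 4 libraries of a time, which cannot be called at that time. The 13 regions lost at all 3 times included those near Best4 and smash, an intergenic region at the start of lncRNA:CR46253 in an Rt1b element (2L, 23239177 to 23239287) and a HeT-A element on chromosome 4 (1293096 to 1293256).

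Transposable elements were more frequent the more often a region was parted. Annotated elements overlapped 3.94% of regions gained at 1 time, 7.99% at 2 times and 17.9% at all 3 (all 3 against 1 time, odds ratio 5.30, Fisher's exact p = 8.87e-05). Among lost regions the shares were 4.54%, 16.3% and 61.5% (odds ratio 33.6, Fisher's exact p = 3.9e-08), while 2.56% of all regions overlapped an element. All 13 regions lost at each time were in both L3 libraries, and 17 of the 56 gained at each time were in at least 1. The labels describe regeneration and control discs as separate genotypes, so damage and genotype coincide in these comparisons.

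**Figure D3:**
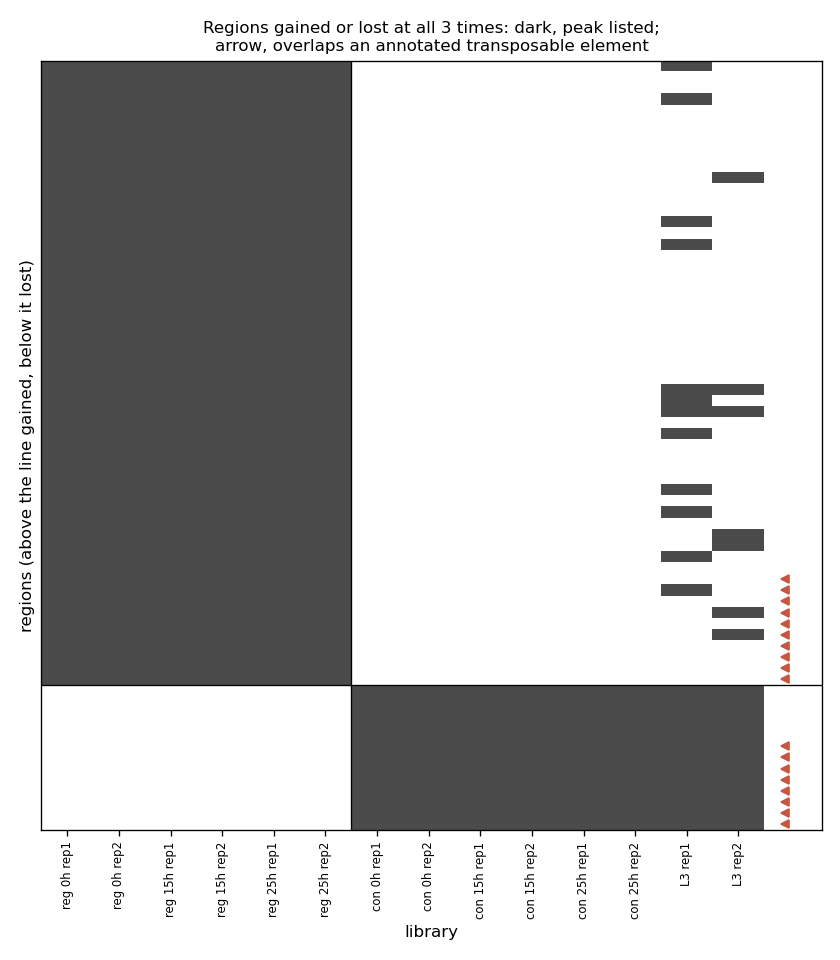
Presence of a nucleosome-free peak (dark) in each library (columns, the 6 regenerating left of the vertical line) for the 56 regions gained and the 13 lost at all 3 times (from top to bottom). Arrows mark overlap with an annotated transposable element, 10 of the 56 gained and 8 of the 13 lost regions.

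None of the 19 gene lists had more genes with a gained or lost region than matched random lists (permutation tests, all adjusted p = 1; 0 lists at an unadjusted p under 0.05 in either direction). Of 14 JNK pathway genes, whose kinase cascade responds to damage, 4 had a gained and 3 a lost region (2 had both), among them a gained region at the start of the kinase gene slpr at 25 h and gained intronic regions of msn at 0 h. Of 17 damage-response genes 6 had a gained and 1 a lost region: chinmo gained a region 1576 bp from its start at 25 h (2L, 1649547 to 1649682), Timp one 2019 bp from its start, in a coding exon of its host gene Syn, at 15 and 25 h (3R, 10215026 to 10215331) and Atf3 an intronic region at 0 h. Pvr, which encodes a PDGF and VEGF receptor, lost a region 233 bp from its start at 15 h (2L, 8240111 to 8240236) and gained a 5′ UTR region at 25 h. A neighbouring 5′ UTR region of Pvr (2L, 8239372 to 8239588), in all 8 undamaged libraries, was lost at 15 and 25 h, and an intronic one was gained at 0 h and lost at 15 h. Of 9 measured apoptosis genes none had a gained region, against 2.33 expected, and hid had a lost one. In the JAK/STAT list, an intergenic region 3703 bp from the cytokine gene upd2 (X, 18239407 to 18239581) was gained at 0 and 25 h, and a region at a start of Stat92E (3R, 20552272 to 20552355) was lost at 15 h.

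Of 16 Wnt pathway genes 8 had gained regions, among them a coding exon of wg at 0 h (2L, 7312926 to 7313164) and the 5′ UTR of pan, the pathway's DNA-binding factor, at 25 h (chromosome 4, 69271 to 69398). Lost regions were found for 3, including a roo element in an intron of Wnt6. Of 12 Dpp pathway genes 5 had gained and 4 lost regions, the latter with Mad and the receptor gene tkv at 25 h. Of 23 wing patterning factors 12 had gained regions, such as intronic ones of ap and ct, and 6 lost ones, such as one 1294 bp from nub at 15 h (2L, 12586093 to 12586331). Of Hippo genes 3 had gained and 2 lost regions (14 measured), of EGFR genes 4 and 1 (9) and of Notch genes 2 and 2 (10). The numbers were 8 and 3 (14) for ecdysone response genes, 3 and 2 (15) for cell cycle genes, 3 and 0 (10) for sensory and proneural genes and 2 and 1 (7) for innate immunity genes.

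Of 20 oxidative and heat stress genes 4 had gained and 2 lost regions. Here the 5′ UTR of the chaperone gene Hsp26 was gained at 25 h (3L, 9377327 to 9377489), and the 5′ UTR of Sod2, the mitochondrial superoxide dismutase, was lost at 0 h and gained at 25 h (2R, 16773871 to 16773971). Markers of other cell types that a disc can carry gave gained and lost regions in 1 and 0 of 7 hemocyte genes, 3 and 1 of 9 myoblast genes, 3 and 3 of 8 tracheal genes and 1 and 1 of 2 fat body genes. Of the 151 gained or lost regions of listed genes, 12 passed the local form of the depth filter, among them those named here of Mad, pan, chinmo, Stat92E, Hsp26 and Sod2, the Wnt6 element, the lost Pvr region 233 bp from the start and the nub region. The neighbouring Pvr 5′ UTR region lost at 15 and 25 h did not pass.

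Each of the 10 genes fixed for description had regions in all 12 time-course libraries, such as 3 of 9 for hid, 3 of 10 for wg and 6 of 14 for nub. All 4 peaks within 5000 bp of the rpr start were in each of the 12 time-course libraries, as were both regions of Ets21C and the only one of Ilp8. Of 10 regions of upd3, a cytokine gene of the damage response, 3 were in all 12. One 4811 bp from the start was gained at 15 h, one 184 bp from the start was lost at 25 h. An intronic one (X, 18278877 to 18279128) was in all 6 regenerating libraries, in 1 of 2 controls at each time and in both L3 libraries. The region at the upd3 start (X, 18277179 to 18277297) was in all 8 undamaged and 4 of the 6 regenerating libraries. None of the regions of rpr, puc, Mmp1, Ilp8 or Ets21C was gained or lost.

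Some gained regions lay at promoters, such as those of speck, slpr and Hsp26, but promoters were less frequent among gained and lost regions than among the others. Promoters made up 20.2% of gained regions over the 3 times and 36.8% of the other regions tested (Mantel-Haenszel odds ratio 0.430; Fisher's exact p = 3.34e-33, 2.97e-40 and 3.57e-22 at 0, 15 and 25 h). Of lost regions they made up 21.0% against 36.3% (odds ratio 0.471; Fisher's exact p = 2.35e-08, 6.38e-10 and 6.89e-12). The other regions tested included those with a peak in all 4 libraries of a time (15581, 16324 and 16577 at 0, 15 and 25 h). These cannot be called gained or lost, and 42.1% of the regions in all 14 libraries were promoters. Part of the difference therefore follows from the presence rule. Introns held 41.2% of gained and 40.5% of lost regions, and intergenic sequence 34.9% and 39.1%. Regions found in 1 library of each group, a comparison added after the data were seen, had 23.8% promoters (gained, odds ratio 0.843, Fisher's exact p = 0.00585; lost, 0.868, p = 0.106). Under the genome form of the depth filter the odds ratios were 0.578 for gained and 0.620 for lost regions, and under the local form 1.02 and 1.01.

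The AP-1 motif, bound by the JNK-activated factors Jra and kay, was in 2.13% of gained regions and 2.61% of the other tested regions (odds ratio 0.811, Fisher's exact p = 0.154, adjusted p = 0.386). By the same exact test, the motifs of GAGA factor (odds ratio 0.637, adjusted p = 8.20e-08), Grainyhead (0.652, adjusted p = 2.97e-06), M1BP (0.551, adjusted p = 0.000598) and DREF/BEAF (0.682, adjusted p = 0.0124) were less frequent in gained regions. Those of Mad (1.28) and POU factors (1.43, both exact tests with adjusted p = 0.0499) were more frequent. The other tested regions again included those with a peak in all 4 libraries of a time, which cannot be called. Differences from them, for gained and lost regions, can therefore follow in part from the presence rule. Over 12 settings the odds ratio of Mad ranged from 0.445 to 1.39 and passed in 2, and those of M1BP (0.536 to 2.43), DREF/BEAF (0.628 to 2.17) and GAGA factor (0.635 to 1.06) also lay on both sides of 1. Grainyhead (0.481 to 0.769, passing in 10) and POU factors (1.14 to 1.97, passing in 6) kept their direction. Lost regions, by the exact test, more often held the motifs of Pangolin, the Wnt effector (4.15% against 2.26%, odds ratio 1.87, adjusted p = 0.00709), and Scalloped, the TEAD factor of the Hippo pathway (11.1% against 8.50%, odds ratio 1.35, adjusted p = 0.0268). They less often held those of GAGA factor (0.670) and Grainyhead (0.656, exact tests with adjusted p = 0.0119 and 0.0132). Over the 12 settings Pangolin (1.34 to 2.54, passing in 8), Scalloped (1.20 to 1.39, passing in 5) and Grainyhead (0.383 to 0.925, passing in 8) kept their direction in lost regions, and GAGA factor (0.568 to 1.08) did not. Against regions found in 1 library of each group no motif passed for gained regions (Fisher's exact test with adjustment, 3 motifs at an unadjusted p under 0.05), and Pangolin alone passed for lost ones (odds ratio 1.89, adjusted p = 0.0324).

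In undamaged discs, 6 of the 20 oxidative and heat stress genes had a region that opened between 0 and 25 h, against 2.33 expected (permutation p = 0.0204, adjusted p = 0.388), and no list passed. The 5′ UTR region of Mad and the gypsy5 region near Best4 were in both control libraries at each time. In all, 703 nucleosome-free regions opened and 466 closed, and the other splits of these 4 libraries parted 975 and 669. Under the local form of the depth filter 13 opened and 102 closed. From 0 to 15 h 988 opened and 231 closed in controls, in all 1219, while another split of these libraries parted 1468 (452 against 244 and 125 against 62 under the genome and local forms of the filter). From 15 to 25 h 246 opened and 914 closed, and the other splits parted 1038 and 671. The genome form of the filter left 51 and 327 (378 in all, higher other split 239) and the local form 4 and 208 (212, other 58). In regenerating discs these forms left 194 and 127 (321, other 284) and 61 and 39 (100, other 118) over this step. Regions gained at 25 h are by the call absent from both 25 h controls. Closing in controls and opening with damage were therefore not told apart. In regenerating discs the numbers from 0 to 25 h were 515 and 552, in all 1067, and the other splits parted 989 and 787, but under both forms of the filter another split parted more (340 against 288 and 140 against 98). There 146 opened and 142 closed under the genome form and 62 and 36 under the local form. Without 0 h control replicate 1 or 2 the numbers in controls from 0 to 25 h were 1320 and 2211 or 2197 and 1218, and without 25 h control replicate 1 or 2 they were 1911 and 747 or 1706 and 1183.

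L3 discs shared with all controls the regions near Best4 and smash and in the 5′ UTR of Mad, and lacked, as all controls did, those of speck, Ptp99A, l(3)80Fj and HGTX. They had 888 regions absent from both 0 h controls, and lacked 123 that both had, in all 1011, while the other splits parted 921 and 865. Under the genome and local forms of the depth filter another split parted more, 270 against 188 (139 and 49) and 90 against 38 (12 and 26). The numbers against the 15 h controls were 649 and 478, and 119 and 206 or 6 and 137 under the genome or local form. Against the 25 h controls they were 1200 and 410, and 426 and 218 or 133 and 104. Without L3 replicate 1 or 2 the total against the 0 h controls was 2370 or 3124, and without 0 h control replicate 1 or 2 it was 2594 or 3894.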

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

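The tests of the depth explanation, of transposable elements, of listed genes and of opposite calls below were chosen after the results were seen, and the comparison over combined splits before. Some regions were called in opposite directions at 2 times. Their number was compared with independent lists by Fisher's exact test over regions, added after the data were seen, but the difference between the times at a region and its source were not tested. At 0 and 15 h 26 regions were gained and then lost and 4 lost and then gained, where independent lists would give 12.5 and 1.71 (exact p = 0.000389 and 0.0928). At 0 and 25 h the numbers were 11 and 10 (6.11 and 3.07, exact p = 0.0576 and 0.000964), the latter with the 5′ UTR of Sod2. At 15 and 25 h 14 were gained and then lost, among them a coding exon of Wnt10, and 39 lost and then gained (2.77 and 11.8, exact p = 7.88e-07 and 5.61e-11). Independent lists were taken over all regions tested at both times. These include regions with a peak in all 4 libraries of a time, 16324 at 15 h and 16577 at 25 h, which cannot be called at that time. Regions near the detection limit can therefore recur in any direction, so these p-values do not show reversals beyond that.

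Chance assignment of libraries gave as many parted nucleosome-free regions in 1 of the 27 combined splits, the real one (4166, highest other 4007). This share of 0.037, the smallest possible, lies below 0.05 for the listed peaks. Under the local form of the depth filter the share was 0.0741 (562 against 575). The replicate block gave 0.125, the smallest it allows, so that form cannot fall below 0.05. The libraries also differ in depth, so a technical grouping is not excluded. For mononucleosome regions 5 of 27 splits gave as many (2093, highest other 2321), so chance is not excluded for the sum.

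The surplus of gained over lost regions may come from the deeper regenerating libraries. At 15 h the ratio of gained to lost fell from 1.26 to 0.298 under the local form of the depth filter (95% exact binomial interval 0.206 to 0.423). Under the genome form it fell to 0.570. Both lie below 1, the outcome set for depth, but removing depth alone would bring the ratio towards 1 and not past it. Other splits of the same libraries were more uneven, at 7.11 and 3.24 under the local and genome forms, so the ratio cannot decide. Typical summit pile-ups at regions common to all libraries were 47 and 53 in regenerating and 37 and 63 in control libraries. Simulated libraries that differed in depth alone gave 190 gained and 281 lost, not a surplus of gains. Depth therefore stays open there. At 0 h the ratio fell from 6.49 to 0.717 (0.444 to 1.15) under the local form and stood at 2.35 (1.80 to 3.08) under the genome form. These lie below the 5.13 and 4.03 that other splits reached, so depth and damage cannot be told apart there, although simulated depth alone gave 552 gained and 57 lost. At 25 h the ratio was 4.77 (3.52 to 6.56) under the local and 3.34 (2.73 to 4.11) under the genome form. Other splits of the same libraries reached 3.71 and 1.57. Simulated depth alone gave 196 gained and 275 lost at 25 h, but under the local form the interval takes in the other split, so a technical source stays open beside damage and genotype. The simulated counts carried counting error only, whereas the other splits of the real libraries parted 1155 and 763 regions at 15 h. The simulation therefore cannot count against depth at 15 or 25 h.

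Regions parted at each of the 3 times may reflect repeats that differ between the fly stocks. The overlap with transposable elements rose with the number of times, with odds ratios of 5.30 for regions gained and 33.6 for regions lost at all 3 times, as a difference in element insertions would give. Elements do not cover the other 46 gained and 5 lost regions, which stay open. The response to damage as the source was tested on genes of the JNK, damage-response, apoptosis, JAK/STAT and Wnt lists: 0 of the 56 regions gained at all times were assigned to them and 24 of the 2310 gained at 1 time (odds ratio 0, Fisher's exact p = 1), which is too few to decide. Since the labels give damaged and undamaged discs different genotypes, stock and damage cannot be told apart for these regions.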

How the results depend on the processing

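The depth filter, the removal of regions in transposable elements and the comparison with regions found in 1 library of each group were chosen after seeing the data, and the other settings before. Counts of gained and lost regions depend on depth, since a region near the detection limit is listed in deeper libraries only. With equal list lengths 572 regions were gained and 430 lost at 0 h and 647 and 517 at 25 h, which by construction removes part of the surplus. The asymmetric threshold gave 787 gained and 97 lost at 0 h, 405 gained at 15 h, 158 lost at 25 h, and 387 opened and 244 closed in controls, and summit clusters gave 362 lost at 0 h and 445 at 25 h. The local form of the depth filter left 33 gained and 46 lost at 0 h, 42 and 141 at 15 h, 248 and 52 at 25 h, 13 opened and 102 closed in controls, and 38 between L3 and 0 h controls. The genome form left 190 and 81, 131 and 230, 414 and 124, 170 and 204, and 188. Both filters keep fewer regions by construction, and the cause of the other shifts was not tested.

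Leaving out 1 library relaxes the criterion by construction, and gave 1983 to 3203 gained and 341 to 1356 lost at 0 h, 1218 to 2446 and 968 to 2254 at 15 h, 1925 to 3021 and 569 to 1290 at 25 h, 1320 to 2197 opened and 747 to 2211 closed in controls, and 2370 to 3894 between L3 and 0 h controls.

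The regions parted over the 3 times kept the smallest possible exact permutation share, 0.037, in 7 settings (1170 to 5110 regions), and the local form of the depth filter gave 562 with a share of 0.0741. Shared gains numbered 34 to 462 and kept exact permutation p = 0.00463 in all 8 other settings. No gene list passed in any setting. The odds ratio for promoters turned under the local form of the depth filter, to 1.02 for gained (p = 0.868) and 1.01 for lost regions (p = 0.939), by Mantel-Haenszel pooling rather than an exact test, and the cause was not tested. The genome form kept it below 1, at 0.578 (p = 1.06e-10) and 0.620 (p = 1.14e-05), likewise pooled and not exact. Of 20 motifs in gained regions 3 passed with stricter peaks and 3 with equal list lengths (5 each at an unadjusted Fisher's exact p under 0.05), 1 under the genome form (4), 2 away from starts (4) and 0 against regions in 1 library of each group (3), for causes that were not tested. The difference in peak number was 1719.5 with stricter peaks (exact permutation p = 0.0833, cause not tested). The regions of highest rank per time, 45 entries from 25 gained and 11 lost regions, kept their call in 179 of 180 tests. Stricter peaks, equal list lengths and the cover rule only remove peaks, so they cannot add one to the group that lacked it. Peaks of high rank are also unlikely to be removed by stricter peaks or equal list lengths. These settings could therefore hardly change a call. With regions from summit clusters 44 entries kept their call and 1 was weaker. The other named regions were not tested singly.

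Replicates of different groups share only a number in the labels. Same-numbered libraries did not deviate together (correlations −0.0153, 0.0395 and −0.00240 at 0, 15 and 25 h for nucleosome-free and −0.0938, 0.0119 and −0.00284 for mononucleosome regions). With the replicate number as a replicate block, the 4166 nucleosome-free regions had an exact permutation share of 0.125, the smallest that 8 splits allow, and the 2093 mononucleosome regions 0.5.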

Other observations

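The comparison across all libraries was chosen after the data were seen. In all 6 regenerating and none of the 8 undamaged libraries there were 39 nucleosome-free regions, such as those at speck, Ptp99A, HGTX and l(3)80Fj, and 13 showed the reverse, such as those near Best4 and smash. The total of 52 compares with at most 9 in the others of 100 splits into groups of 6 and 8, drawn at random beside the real one. Annotated transposable elements overlapped 7 of the 39 and 8 of the 13. Gained regions made up 13.1% of the tested regions on chromosome 4 and 12.2% on X, against 9.60 to 10.7% on the other arms, and lost regions 2.36% on chromosome 4 and 4.18% on X.

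One hypothesis was that damaged discs develop later, so that regions gained with damage would be those that close with time in controls. The test, chosen after the results were seen, used control libraries that did not enter the call. Of regions gained at 15 h, 21 closed and 39 opened in controls from 0 to 25 h, and of those lost 23 closed and 16 opened (odds ratio 0.375, Fisher's exact p = 0.0236), the opposite of what a delay would give. Of regions gained at 25 h 20 closed and 125 opened from 0 to 15 h, and of those lost 0 and 9 (Fisher's exact p = 0.606). By the call, regions gained at 25 h were absent from both 25 h controls. The 125 had thus opened in controls by 15 h and were no longer listed there at 25 h. A delay could give these as well as the 20, so the contrast cannot decide and a delay stays open at that time. Depth enters both calls, so the test could also follow the libraries.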
